A study of Mus musculus with 4 samples.

How the data were processed

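DNase-seq libraries of primary B cells from female B6CASTF1/J mice, 2 months old, were analysed as 4 biological replicates of 1 group. The replicate numbers and the cell type were taken from the labels. The labels give the libraries separate biosample records under 1 donor record, and give neither the tissue nor the sorting of the cells. p-values over libraries therefore measure the spread between these 4 libraries, which may be partly technical.

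The files start from steps made by the authors. The title of the series marks it as superseded by another, whose files were not used here and may differ. Per the file headers and the notes deposited beside the files, peaks, footprints and the per-base false discovery rate were each derived from the filtered alignments of 1 library, on the mouse assembly mm10, so nothing was pooled. The aligner, the peak caller, the footprint caller and their thresholds are not given in the sources used here. The deposited peak lists, 2 per library, carry a signal per peak, which is never negative. It was read as a density of cleavage scaled to library depth, because 99.9969% to 99.9988% of the signals of a library lay within 0.05 steps of a whole multiple of a step. The step differed between libraries, at 0.00662, 0.00561, 0.00505 and 0.00638 for replicates 1 to 4. The relative depths given are the largest step divided by each step, and no read number can be had from them. This signal is the authors' value and was used to rank or filter peaks within a library, to compare classes of peaks by their medians, to give the level of the strongest regions and, on the log2 scale, to correlate libraries over shared regions. The deposited footprints carry the FDR 0.01, the same for every footprint, and the deposited per-base file carries an FDR for positions under 0.05.

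The larger peak list of each library was used, and the smaller as a stricter alternative. Every peak of the smaller list held a position with an FDR of 0.001 or less, and 98.3% of the smaller list of replicate 1 overlapped the larger. Coordinates are those of mm10, equal to GRCm38, and are given counting from 1. None of the 1856770 deposited peak and footprint intervals ran past the end of a GRCm38 chromosome. Genes came from GENCODE M21, with 21827 protein-coding genes and 41406 TSSs. The reference holds the genome of 1 parental strain, and how reads of the CAST/EiJ genome were treated is not given in the sources used here. Sites that differ between the strains may be under-counted.

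Overlap meant 1 bp or more. Regions were the merged peaks of all libraries. A peak was assigned by its midpoint to a promoter, within 1 kb of a TSS, and otherwise to exon, intron or intergenic sequence in that order. A promoter was called open in a library where a peak overlapped the sequence within 1 kb of a TSS of the gene. Its percentile is the rank of its strongest peak among all peaks of that library. Peaks were also counted in gene spans extended by 10 kb on each side.

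The gene lists, 21 of them with 301 genes, the 27 motifs, the tests, most alternatives and the rule for naming genes were chosen before the data were examined. The lists cover B cell receptor and surface, B lineage transcription factors, MHC class II, homing and survival receptors, early B and V(D)J recombination, germinal centre, plasma cell, marginal zone and B1, activation and immediate early, innate sensing, T cell, NK cell, myeloid, dendritic cell, erythroid and megakaryocyte, stem and progenitor, neuron, hepatocyte, striated muscle, fibroblast and endothelium, and housekeeping genes. The rule named, in each list, up to 4 members open in all 4 libraries with the strongest promoter peaks, up to 3 open in none, those with the most peaks in their extended span first, and members open in 1 to 3 libraries where there were at most 3. Outside the lists it named the 10 genes with the most peaks in the extended span, the 10 with the strongest promoter peaks, the 5 strongest regions of all 4 libraries and the strongest promoter peak of each named gene. Not every gene that the rule picked is reported here.

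Each list was compared with 100000 random lists of protein-coding genes outside it, in a two-sided permutation test. For promoters, random lists were matched on 10 equal classes of the CpG ratio (observed over expected, within 500 bp of the main TSS). For extended spans they were matched on 10 classes of gene length and, within these, 3 classes of the CpG ratio. p-values were adjusted over the 21 lists by the method of Benjamini and Hochberg, with 0.05 as the threshold. The test compares lists within these libraries, and genes are not independent replicates. Values with 1 number per library were tested with an exact sign-flip permutation test, two-sided, whose smallest p with 4 libraries is 0.13. Such a test cannot reach 0.05. Chromosome densities were taken over sequence of known bases. Expected location shares came from points spaced evenly over the genome.

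Motifs were counted as consensus matches on both strands. A match belonged to a footprint where its midpoint lay in it. Outside footprints meant all other sequence in the peaks of the same library, peaks without a footprint included. To each count 0.5 was added. The log2 of matches per Mb inside over outside was reduced by the same value of the reversed, not complemented, consensus. The same was done for distal over promoter peaks. Reversal keeps the base content but turns CG into GC, so CpG content is not controlled. Adjustment was over the 27 motifs. Near copies of a region were matches elsewhere in the GRCm38 primary assembly, found with BLAST+ 2.17.0, of at least 90% identity over at least 80% of the region (e-value 1e-10, at most 50 alignments kept per sequence, low-complexity sequence masked for seeding only). Counts of copies are therefore lower bounds. Shares have exact binomial intervals, which cover counting error only.

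Some of the steps were tested on simulated data. Of unchanged lists of 16 genes drawn from the 21827 genes, 2.0% had p under 0.05. Of unchanged lists of CpG-rich genes this share was 2.75% with matching and 64.5% without. Of lists raised by 40 percentage points, 85% had p under 0.05. These shares are before adjustment. Each simulated gene was open or closed independently of the others, and only the promoter test was simulated. Lists of clustered genes and the test of extended spans were therefore not covered. In 6100 overlap answers compared with a direct search, 0 differed. A planted log2 motif ratio of 3.00 was recovered as 2.96, and the reversed consensus gave 0.12.

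Alternatives were promoters within 500 or 2500 bp, the stricter list, the same number of peaks in every library, random lists not matched, the gene span alone or with 50 kb, reciprocal overlap of 50%, the wider 50% of footprints, the same number of footprints, flanks of 50 bp as the outside of footprints, no reversed consensus, and each library left out. Chosen after seeing the data were merging of overlapping intervals, leaving out genes over 2 Mb, leaving out peaks with at least 50% repeat sequence, and the ratio of receptor loci to the genome with its exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.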

Results

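DNase-seq was used to map accessible chromatin in B cells from adult female mice of the hybrid strain B6CASTF1/J. DNase I cleaves DNA that is not protected by nucleosomes or bound proteins, so peaks of cleavage mark open chromatin, and short protected stretches inside them, called footprints, mark sites where proteins may sit. B6CASTF1/J mice are the first-generation offspring of a laboratory C57BL/6J and a wild-derived CAST/EiJ parent, so each cell carries 1 genome of each strain. The labels give the mice as virgin and 2 months old. The data consist of 4 libraries, labelled biological replicates 1 to 4, all in 1 group, B cells, with no second condition. The comparisons made here are therefore between libraries, between classes of genes and between places in the genome. The number of reads per library is unknown. The peak signals were whole multiples of a step that differed between libraries, and taken as the worth of 1 cleavage count the steps put replicate 3 deepest, at 1.31 times the depth of replicate 1. Replicates 2 and 4 were at 1.18 and 1.04 times.

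B cells of these mice had on average 95064 ± 12071 accessible sites per library (SD, n = 4). The sites covered 21 ± 2.92 Mb, or 0.793% ± 0.110 of the genome, and had a median width of 200 bp. Of the 137336 regions with a peak in any library, 59194, or 43.1%, had a peak in all 4 libraries. Regions at promoters made up 29.1% of these shared regions and 13.5% of the 49192 regions found in 1 library alone. Replicate 1 had the fewest peaks, 81018, and replicate 3 the most, 110324. Replicates 2 and 4 had 92689 and 96225. A library's peaks overlapped a peak of another library in 77.0% ± 6.49 of cases (SD, n = 4), from 68.7% for replicate 3 to 84.5% for replicate 1. The peaks found in 1 library alone were weak, with a median signal of 0.276 ± 0.0147 against 1.40 ± 0.206 for peaks in the regions of all 4 libraries. Across the 59194 shared regions, which are not independent replicates, the log2 signals of the 6 pairs of libraries had Pearson correlations from 0.950 to 0.982.

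**Figure D1:**
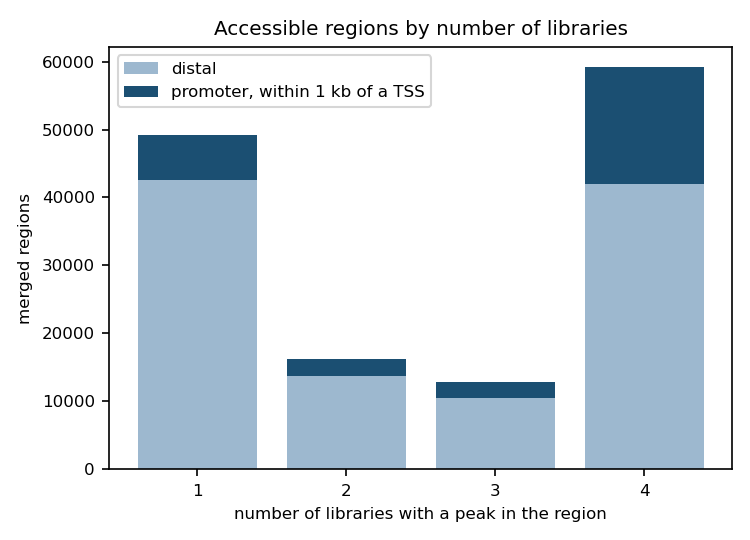
Number of merged accessible regions (vertical axis) by the number of libraries with a peak in them (horizontal axis), divided into promoter regions, within 1 kb of a protein-coding TSS, and distal regions. The bars hold 49192, 16173, 12777 and 59194 regions for 1, 2, 3 and 4 libraries.

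Promoter sites were found again in the other libraries more often than distal sites when all peaks were pooled. Of promoter peaks, 77.1% ± 3.52 had a peak in all 3 other libraries, against 62.4% ± 9.78 of distal peaks (SD, n = 4). The difference, 14.7 ± 6.60 percentage points, had the same sign in 4 of 4 libraries (exact sign-flip permutation test, two-sided, p = 0.13, the smallest p that 4 libraries allow). Promoter peaks were stronger, at a median signal of 2.06 ± 0.271 against 0.685 ± 0.0720 in introns, and among peaks of like signal the difference was not kept. Within 5 equal classes of peak signal, promoter minus distal was 1.85 ± 4.88 points in the weakest class. It was -1.20 ± 12.1, -3.15 ± 7.78, -8.60 ± 0.812 and -1.90 ± 0.301 points in the next 4. The lower 3 classes were negative in replicates 1 and 2 but, in replicates 3 and 4, positive, and the upper 2 were negative in 4 of 4 libraries. In the strongest class, 97.5% ± 0.357 of promoter and 99.4% ± 0.108 of distal peaks had a peak in all 3 other libraries.

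Accessible sites lay at promoters far more often than the genome as a whole. Promoters, taken as sequence within 1 kb of the TSS of a protein-coding gene, held 25.7% ± 2.17 of peaks (SD, n = 4) and 2.03% of points spaced evenly over the genome. Other exonic sequence held 5.72% ± 0.176 of peaks against 3.12% of points. Introns held 33.1% ± 1.70 of peaks against 34.7%, and intergenic sequence 35.5% ± 0.537 against 60.2%. The distal peaks lay a median of 21 ± 0.69 kb from the nearest TSS. Repeats marked in the reference made up at least 50% of the bases of 10.1% ± 0.628 of peaks, while 36.4% of the genome is so marked. The promoter share depended on its definition, at 18.3% within 500 bp of a TSS, and it was 31.4% in the stricter peak list.

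Every promoter of the B cell receptor and surface list was open in every library, as was every promoter of the B lineage transcription factor list and the MHC class II list. The first list holds 22 genes of the B cell receptor, its signalling and the B cell surface. It had 22 open in all 4 libraries, against 37.3% in random lists of genes with promoters of like CpG content. Its strongest promoters included Cr2, the complement receptor CD21, Cd24a, Cd79a, the signalling chain of the B cell receptor, and the kinase gene Lyn. The strongest promoter peak of Cr2 ranked at percentile 96.2 ± 1.12 of all peaks (SD, n = 4), where 100 is the strongest, and that of Cd79a at 93.5 ± 2.05. All 17 transcription factor genes were open, against 67.5% in random lists. Among them were Klf2, a regulator of lymphocyte migration, at percentile 99.9 ± 0.0286, Ets1 at 99.6 ± 0.204, Tcf3, which encodes E2A, at 96.6 ± 0.557, and Ebf1, a factor that sets B cell identity, at 96.3 ± 0.741. All 10 MHC class II genes, which serve antigen presentation to helper T cells, were open, against 28.3%. H2-DMa stood at percentile 99.4 ± 0.163, H2-DMb2 at 97.8 ± 0.886, H2-Aa at 96.3 ± 1.18 and Cd74, the invariant chain, at 95.2 ± 1.66. The permutation test, two-sided with 100000 random lists and adjustment over the 21 lists, gave an adjusted p = 0.000105 for the receptor and MHC lists, from the smallest p it can give (2e-05), and 0.000252 for the transcription factors.

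The promoters of 5 further lists were also open more often than those of matched random lists. The 13 genes of the B cell homing and survival list were open in 98.1% ± 3.85 of cases (SD, n = 4) against 42.6% (adjusted p = 0.000105, permutation test). They include Cxcr4 at percentile 99.0 ± 0.447, Ccr7 at 92.5 ± 2.04, Tnfrsf13c, which encodes the BAFF receptor, at 90.3 ± 1.31, and Cxcr5 at 87.3 ± 3.22, while Ccr6 had a promoter peak in 3 libraries. Innate sensing genes were open in 96.2% ± 4.44 against 50.6% (adjusted p = 0.000105, permutation test), with Irf7 at percentile 92.1 ± 1.60 and Tlr9, a sensor of CpG DNA, at 88.0 ± 2.17, and with Tlr7 open in 2 libraries. Marginal zone and B1 genes were open in 95.8% ± 4.81 against 64.4% (adjusted p = 0.00840, permutation test). Notch2, which marginal zone B cells need, stood at percentile 97.2 ± 0.617 and Dtx1 at 90.6 ± 0.824, while Zbtb32 was open in 2 libraries. All 16 activation and immediate early genes were open against 79.6% (adjusted p = 0.0359, permutation test), among them Tnfaip3 at percentile 99.6 ± 0.108, Jun at 99.1 ± 0.598, Egr1 at 98.5 ± 0.598 and Nfkbia at 98.3 ± 0.258. With promoters widened to 2500 bp, this list's adjusted p was 0.0507. All 16 housekeeping genes were open against 80.7% (adjusted p = 0.0330, permutation test), with Actb at percentile 99.9 ± 0.0973 and Ppia at 99.6 ± 0.0996.

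The lists of early B, germinal centre and plasma cell genes did not pass the test. Early B and V(D)J recombination genes were open in 64.6% ± 10.5 (SD, n = 4) against 45.8% (adjusted p = 0.187, permutation test). Of its 12 members 6 were open in all 4 libraries, with Sox4 at percentile 87.2 ± 2.56 and Lef1 at 77.6 ± 2.34. A further 4 were open in 1 to 3 libraries. Dntt, the terminal transferase of V(D)J joining, and Vpreb2, a surrogate light chain gene, had a promoter peak in no library. Germinal centre genes were open in 87.5% ± 5 against 64.2% (adjusted p = 0.0972, permutation test). Bcl6, the master regulator of that stage, stood at percentile 91.0 ± 1.62, while Rgs13 was open in no library and Gcsam in 3. Plasma cell genes were open in 81.2% ± 4.17 against 64.2% (adjusted p = 0.189, permutation test). Edem1, of protein quality control in the endoplasmic reticulum, stood at percentile 99.1 ± 0.341 and Xbp1 at 96.5 ± 0.603. Tnfrsf17, which encodes the plasma cell receptor BCMA, and Jchain, which encodes the joining chain of secreted IgM and IgA, were open in no library. With promoters widened to 2500 bp, the early B list passed at an adjusted p = 0.0255 and the germinal centre list at 0.0153 in the permutation test.

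No list of another lineage or tissue differed from its matched random lists at an adjusted p under 0.05. In the T cell list, 6 of 22 genes were open in all 4 libraries and 14 in none, a mean of 29.5% ± 2.62 against 44.9% (SD, n = 4; adjusted p = 0.174, permutation test). Open members included the adhesion molecule gene Cd2 at percentile 80.8 ± 4.87, Lat at 79.0 ± 2.43, the kinase gene Lck at 70.2 ± 3.72 and Gata3 at 66.2 ± 13.8. Cd247, the zeta chain of the T cell receptor complex, and the kinase gene Zap70 were open in no library. The NK list was at 31.2% ± 4.17 against 30.3%, with Prf1, the gene of perforin, open in all 4 libraries and Nkg7 in none. Myeloid genes were at 37.5% ± 10.4 against 29.9%, with Cd68 at percentile 86.8 ± 3.15, Cebpa at 84.3 ± 2.32 and the neutrophil genes Elane and Mpo open in no library. Dendritic cell genes were at 60% in every library against 53.9%, with Flt3 open in all 4 libraries and Clec9a and Xcr1 in none. Erythroid and megakaryocyte genes were at 20.6% ± 3.40 against 32.4%, with Klf1 and Itga2b open in no library. Stem and progenitor genes were at 62.5% ± 5 against 70%, with Meis1 at percentile 81.8 ± 3.97 and Cd34 and Gata2 open in no library. Neuron genes were at 45.0% ± 8.39 against 61.7%, fibroblast and endothelium genes at 34.6% ± 4.44 against 38.2%, and hepatocyte genes at 12.5% in every library against 29.9%. The adjusted p of these 8 lists, from NK to hepatocyte, lay between 0.174 and 0.976 (permutation test). Striated muscle genes were at 13.5% ± 7.36 against 37.4% (adjusted p = 0.0532, permutation test), with Myod1, Myog and Myl2 open in no library. Other settings called some of these lists lower. Without replicate 2 the muscle list passed, at an adjusted p = 0.0342, as it did in the stricter peak list (0.00833) and with the same number of peaks in every library (0.0314, permutation test). The neuron list passed with the same number of peaks (0.0341), and within 500 bp the erythroid (0.0369), neuron (0.0369) and hepatocyte lists (0.0133, permutation test) did. Against random lists that were not matched on CpG content, 6 further lists passed the test, all with fewer open promoters than expected, and among these the NK and myeloid lists turned direction.

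**Figure D2:**
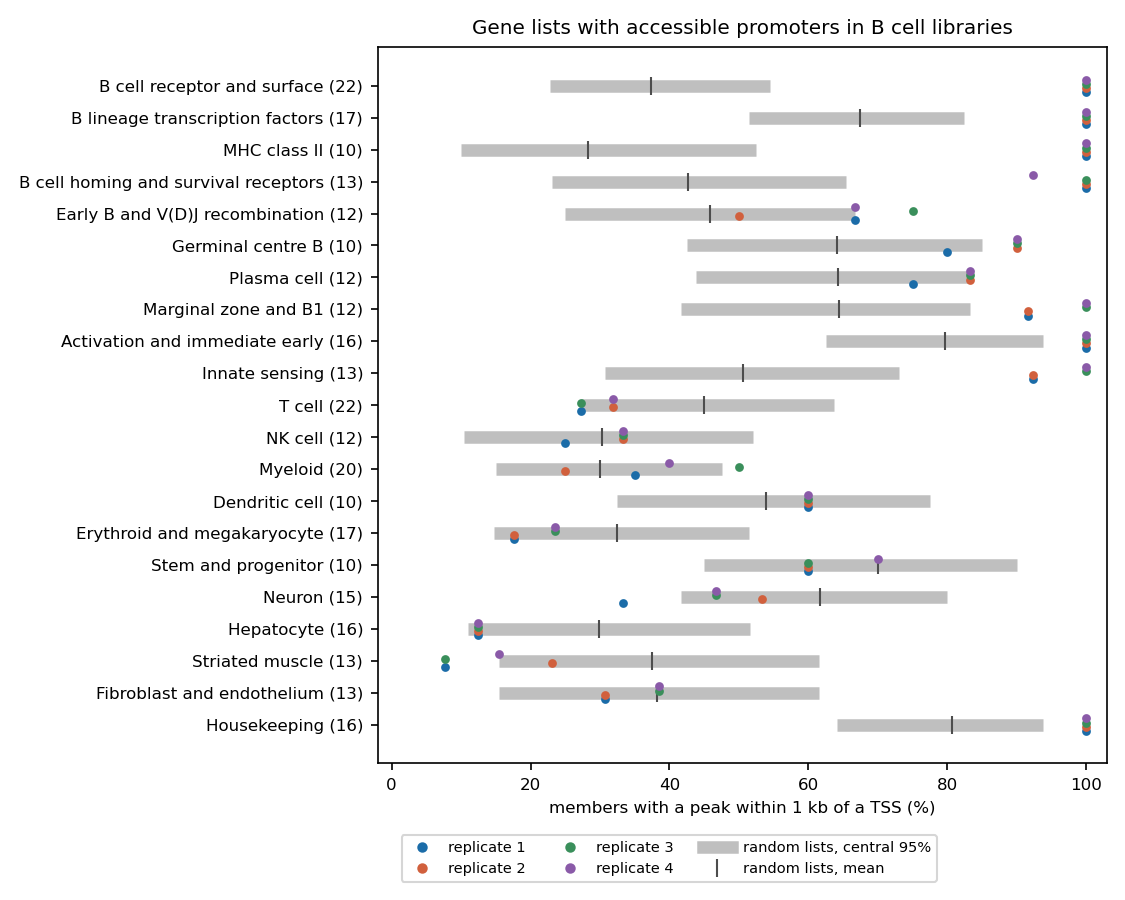
Percent of members of each gene list (number of genes in brackets) with a peak within 1 kb of a TSS (horizontal axis), as 1 point per library, beside the mean and central 95% of random lists matched on promoter CpG content. The B cell receptor, B lineage transcription factor and MHC class II lists sit at 100% in all 4 libraries, outside their random ranges.

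Genes of 4 of the 8 B lineage lists, and activation genes, also had more accessible sites around them. In gene spans extended by 10 kb on each side, MHC class II genes had 24.3 ± 3.29 peaks per gene (SD, n = 4) against 2.76 in random lists matched on gene length and CpG content (adjusted p = 0.00021, permutation test). H2-Aa had 33.5 ± 6.61 and Cd74 34.5 ± 2.65. B lineage transcription factor genes had 24.6 ± 3.08 against 6.21 (adjusted p = 0.0169, permutation test), with Ebf1 at 47.8 ± 10 and Ets1 at 47.8 ± 14.5. Genes of the homing and survival list had 15.5 ± 2.20 against 3.84 (adjusted p = 0.0169, permutation test), with Cxcr5 at 31.2 ± 7.14 and Ccr7 at 26.5 ± 7.94. B cell receptor and surface genes had 10.4 ± 2.13 against 4.06 (adjusted p = 0.0237, permutation test), with Cd79a at 16.2 ± 3.59, and activation genes 13.3 ± 1.80 against 4.78 (adjusted p = 0.00021, permutation test).

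Hepatocyte genes were the 1 list that passed with fewer sites than its matched random lists. They had 1.08 ± 0.0786 peaks per extended gene span (SD, n = 4) against 3.00 (adjusted p = 0.0329, permutation test), with Apob at 2.00, F2 at 1.00 and Fgb at 2.25 ± 0.5. Housekeeping genes had 7.44 ± 1.39 against 4.74 (adjusted p = 0.0329, permutation test). The hepatocyte call was lost with the gene span alone (adjusted p = 0.0562, permutation test) and under 3 other settings, and the housekeeping call in the stricter peak list (0.107), under 2 other settings, without replicate 3 (0.0548) and without replicate 4 (0.0724). Members of some lists share a locus, as the MHC class II genes do, so their extended spans overlap and peaks there count for several members. Random lists were not matched on gene density or on such sharing, so the p-values of these lists may be too small. The other 14 lists did not pass the test. Among these, marginal zone and B1 genes had 9.19 ± 0.916 against 5.49 (adjusted p = 0.0879), early B genes 7.58 ± 0.831 against 3.93 (adjusted p = 0.0692) and T cell genes 5.36 ± 1.19 against 4.16 (adjusted p = 0.284, all by the permutation test). Germinal centre genes (adjusted p = 0.211) and plasma cell genes (0.107, permutation test) were above their random lists too. Striated muscle genes, at 2.33 ± 0.329 against 3.32, NK genes, at 2.04 ± 0.595 against 2.49, and neuron genes, at 5.28 ± 0.600 against 5.55, were below them.

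The immunoglobulin lambda locus was the antigen receptor locus with the most accessible sites per 100 kb. From its first to its last gene segment (chromosome 16, 19061618 to 19260859, GRCm38) it had 11.7 ± 2.26 peaks per 100 kb (SD, n = 4), against 3.59 ± 0.456 for the genome. The heavy chain locus Igh (chromosome 12, 113254830 to 116010093) had 4.27 ± 0.674 and the kappa locus Igk (chromosome 6, 67555497 to 70726966) 4.29 ± 1.17. The T cell receptor loci had fewer than the genome in 4 of 4 libraries, with 2.63 ± 0.525 at Tra/Trd on chromosome 14, 1.95 ± 0.561 at Trb on chromosome 6 and 2.43 ± 0.977 at Trg on chromosome 13. On the log2 scale, Igl stood above the genome by 1.69 ± 0.15 and Igh by 0.25 ± 0.07, both in 4 of 4 libraries (exact sign-flip p = 0.13, the smallest possible). Igk was at 0.22 ± 0.24, above the genome in 3 of 4 libraries (exact p = 0.25). Tra/Trd was at -0.46 ± 0.12, Trb at -0.92 ± 0.33 and Trg at -0.66 ± 0.61 (exact p = 0.13 each). With the same number of peaks taken from every library, Igh was at -0.041 ± 0.15 and Igk at -0.22 ± 0.14. In the stricter list Igh was at 0.13 ± 0.21, with an SD larger than the mean, and Igk was at -0.37 ± 0.44. This ratio and its test were added after the densities were seen.

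Among the V genes of these loci, those of the light chains carried a peak most often. At Igk 49.3% ± 14.1 of 102 V genes overlapped a peak and 7.77% ± 4.04 of 74 V pseudogenes did (SD, n = 4). At Igh the shares were 21.9% ± 2.54 of 113 V genes and 6.48% ± 1.55 of 81 V pseudogenes. At Igl 83.3% ± 19.2 of V genes had a peak, but the locus has only 3 of them. At Tra/Trd 5.22% ± 1.23 of 115 V genes had a peak, at Trb 14.8% ± 4.35 of 22 and at Trg 10.7% ± 7.14 of 7. The strongest shared region of the Igh locus lay 68 bp from Ighv11-1 (chromosome 12, 113981721 to 113981900), at percentile 86.7 ± 2.33. The strongest of Igl lay at chromosome 16, 19146701 to 19146900, in sequence between segments, at percentile 91.3 ± 2.43. Repeated segments of these loci have near copies of one another, and the mapping rule for such reads is not given in the sources used here.

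**Figure D3:**
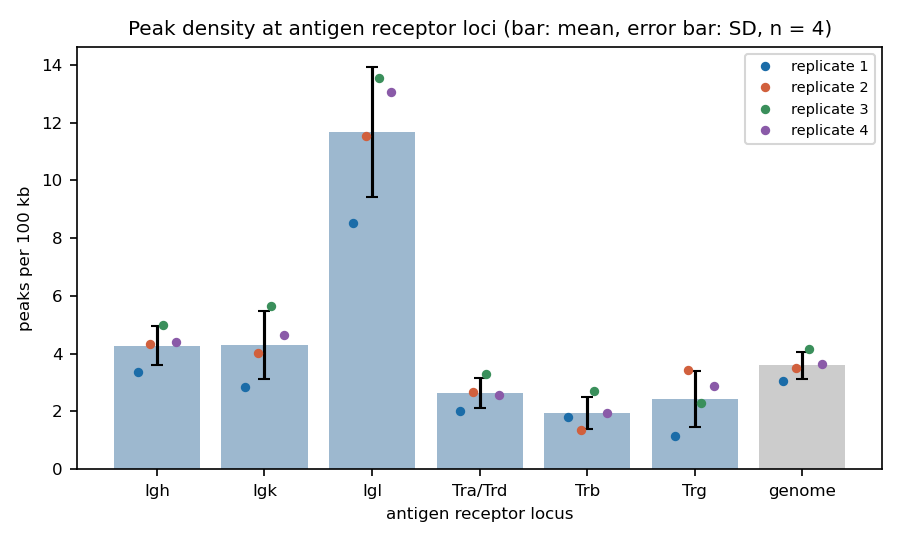
Peaks per 100 kb (vertical axis) from the first to the last annotated segment of each antigen receptor locus, and in the whole genome, as the mean of 4 libraries (bars) with SD (error bars) and each library (points). Igl stands at 11.7 and the 3 T cell receptor loci at 1.95 to 2.63, against 3.59 for the genome.

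The X chromosome had fewer accessible sites than the autosomes. Per Mb of known sequence it had 15.6 ± 1.92 peaks (SD, n = 4), against 38.6 ± 4.91 on autosomes, a log2 ratio of -1.31 ± 0.03 that was negative in 4 of 4 libraries (exact sign-flip permutation test, p = 0.13, the smallest possible). Per protein-coding gene the X chromosome had 2.69 ± 0.332 and autosomes 4.47 ± 0.568. Autosomes ranged from 28.5 ± 3.93 peaks per Mb on chromosome 14 to 61.5 ± 7.27 on chromosome 11, with chromosomes 19 and 17 next at 56.9 ± 7.29 and 50.8 ± 5.59. The mice are labelled female, and 63 ± 13.1 peaks per library lay on the Y chromosome, from 46 to 76. No Y region lay at a promoter.

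Footprints were found at most accessible sites. Each library had 302536 ± 49005 footprints (SD, n = 4), from 246479 in replicate 1 to 357454 in replicate 3, with a median width of 9 or 10 bp. Of these 81.2% ± 1.57 lay in a peak, and 79.8% ± 1.44 of peaks held at least 1. Promoter peaks held 3.62 ± 0.356 footprints each and distal peaks 2.29 ± 0.163. A footprint overlapped one of another library in 54.3% ± 6.51 of cases, less often than a peak did.

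CTCF, NRF1, CRE, RFX and ETS were the motifs most concentrated in footprints. Matches were counted for 27 motifs fixed before the data were examined. Those to CTCF, the factor of chromatin loops and insulators, occurred 1618 ± 151 times per Mb inside footprints (SD, n = 4). Outside footprints, in all peaks of the same library, they occurred 39.0 ± 7.62 times. The log2 ratio of inside to outside was 5.39 ± 0.21. It was 5.96 ± 1.61 after the ratio of the reversed consensus was subtracted, a control for base composition but not for CpG content. Promoter peaks held more footprints than distal peaks, so such ratios can also reflect which peaks carry footprints. With only flanks of 50 bp as the outside, no motif turned sign. NRF1 stood at 5.43 ± 1.44, the CRE of CREB and ATF factors at 3.98 ± 0.13, RFX at 3.80 ± 1.25, the ETS consensus CCGGAAGT at 3.03 ± 0.15, ZNF143 at 2.94 ± 1.99 and YY1 at 1.24 ± 0.05, all on this subtracted log2 scale. The reversed consensus of CTCF, NRF1, RFX and ZNF143 had no match inside or outside footprints in at least 1 library, so their subtracted values are imprecise, and with nothing subtracted they stood at 5.39, 6.70, 3.30 and 2.92.

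Of the motifs of B cell and lymphoid factors, EBF1 stood at 0.86 ± 0.17 on the subtracted log2 scale and at 2.00 with nothing subtracted (SD, n = 4). The octamer of POU2F factors stood at 1.04 ± 0.24, RUNX at 0.93 ± 0.11, SPI1, also called PU.1, at 0.69 ± 0.21, the ETS-IRF composite at 0.42 ± 0.23, the E2A E-box at 0.30 ± 0.04 and the interferon response element at 0.21 ± 0.07. With nothing subtracted, POU2F was at 0.024, RUNX at -0.047, SPI1 at -0.29 and the composite at -0.010, so their excess rests on the depletion of the reversed consensus in footprints. PAX5 at -0.72 ± 0.27 and NF-kB at -1.32 ± 0.16 were below 0 in 4 of 4 libraries, as were AP-1, a general motif, at -0.54 ± 0.11, FOXO at -1.20 ± 0.11 and the T-box at -0.63 ± 0.17. NF-kB was at 0.081 with nothing subtracted. SP/KLF, also general, was at -0.30 ± 0.01 and at 2.94 with nothing subtracted, but its reversed consensus is nearly the same sequence, so the subtraction has no meaning there. MEF2 was at 0.70 ± 0.83, TCF/LEF at 0.48 ± 0.04 and NFY, a general factor, at 0.76 ± 0.11. The motifs of factors of other lineages were HNF4 at 1.85 ± 0.32, the E-box of NEUROD factors at 0.99 ± 0.05, C/EBP at 0.76 ± 0.12, GATA at 0.07 ± 0.07 and the T-box above. With nothing subtracted, HNF4 was at -0.070, the E-box of NEUROD factors at 0.11, C/EBP at 0.60, TCF/LEF at -0.35 and GATA at -1.15. The reversed consensus of HNF4, POU2F and MEF2 had as few as 5, 6 and 8 matches inside or outside footprints of a library. Their subtracted values are imprecise too. In the exact sign-flip permutation test, MEF2 and GATA had p = 0.25 and all other motifs p = 0.13 (adjusted p = 0.135), the smallest that 4 libraries allow, so no motif could pass.

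**Figure D4:**
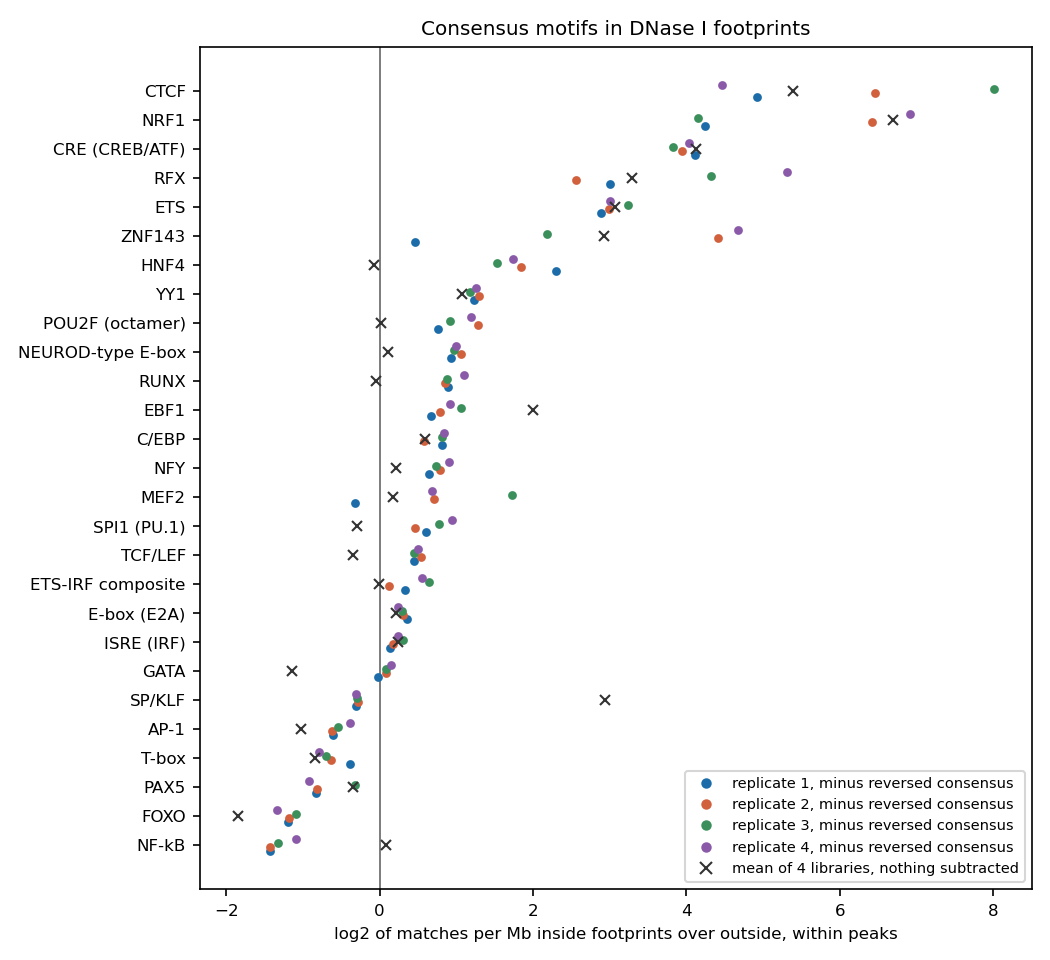
Concentration of 27 consensus motifs in footprints, as log2 of matches per Mb inside over outside footprints within peaks (horizontal axis), after subtraction of the same value for the reversed consensus (1 point per library) and as the mean of 4 libraries with nothing subtracted (crosses). CTCF, NRF1, CRE, RFX and ETS lie above 2 in all libraries, and for SPI1, RUNX, HNF4, GATA, SP/KLF, NF-kB, TCF/LEF and the ETS-IRF composite the cross and the mean of the points differ in sign.

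Distal and promoter sites held different motifs. CTCF was the most distal, with 394 ± 49.9 matches per Mb in distal and 46.3 ± 3.54 in promoter peaks, a log2 difference of 5.19 ± 0.87 after subtraction of the reversed consensus (SD, n = 4). Motifs of some lymphoid factors were also more frequent in distal peaks, with PAX5 at 1.60 ± 0.02, POU2F at 0.98 ± 0.07, SPI1 at 0.96 ± 0.10, RUNX at 0.82 ± 0.06, the ETS-IRF composite at 0.54 ± 0.08 and EBF1 at 0.22 ± 0.05. With nothing subtracted, CTCF was at 3.08 and PAX5 at 0.64, below SPI1 and RUNX at 1.40 each. Promoter peaks held more matches to ZNF143, at -4.79 ± 0.75, the ETS consensus CCGGAAGT, at -3.07 ± 0.01, CRE, at -3.02 ± 0.14, NFY, at -1.88 ± 0.08, RFX, at -1.49 ± 0.48, and YY1, at -0.36 ± 0.08. Each of these had 1 sign in 4 of 4 libraries (exact sign-flip p = 0.13, the smallest possible, adjusted p = 0.141). With nothing subtracted, ZNF143 was at -4.36, ETS at -2.51, CRE at -1.93, NFY at -1.63, RFX at -0.77 and YY1 at -0.73. The reversed consensus does not control for CpG content, so sizes after subtraction depend on it. For CTCF, RFX and ZNF143 it had as few as 3, 1 and 1 matches in distal or promoter peaks of a library. Their subtracted values are therefore imprecise. Other lymphoid motifs went the other way, with NF-kB at -0.30 ± 0.063, FOXO at -0.75 ± 0.085 and the interferon response element at -0.076 ± 0.063, each below 0 in 4 of 4 libraries, but FOXO was at 0.71 and the interferon element at 0.60 with nothing subtracted. MEF2, at -0.19 ± 0.54, had no single sign and was at 1.19 with nothing subtracted, and the E-box of NEUROD factors, of another lineage, was at 0.72 ± 0.053. NRF1 was at 0.32 ± 0.10 after subtraction and at -3.18 with nothing subtracted, where its reversed consensus, with no match on one side in at least 1 library, stood at -3.50.

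The promoter of H2-Aa, an MHC class II alpha chain gene, shows how footprints lay within a B cell promoter. Its strongest peak, in replicate 4, spanned 34287741 to 34288000 on chromosome 17 (GRCm38), centred 48 bp upstream of the annotated TSS, in intergenic sequence. In all 4 libraries a footprint lay within 34287855 to 34287912. It covered the centres of a match to NFY, AACCAATCA (34287865 to 34287873), a match to CRE, TGACGTCA (34287890 to 34287897), and an E-box, CAGCTG (34287905 to 34287910). MHC class II promoters are known to carry adjacent X and Y boxes bound by RFX, CREB and NFY. At the H2-DMa promoter a footprint of all 4 libraries held a CTCF match, CCACCAGGGGGC (chromosome 17, 34135419 to 34135430), in the UTR of the gene.

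**Figure D5:**
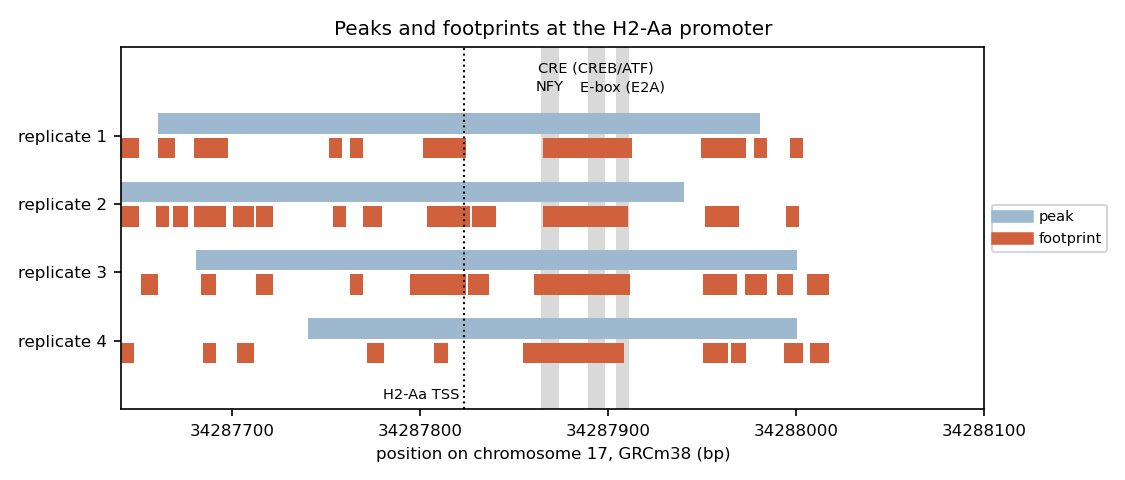
Peaks and footprints of each library at the H2-Aa promoter on chromosome 17 (horizontal axis, position in bp, GRCm38), with the annotated TSS of the gene on the minus strand as a dotted line and matches to the NFY, CRE and E-box motifs as grey bands. A footprint between 34287855 and 34287912 covers the centres of all 3 matches in all 4 libraries.

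The strongest shared region lay in a ribosomal RNA gene. It spanned 39846781 to 39846920 on chromosome 17 (GRCm38), in an exon of the annotated rRNA CT010467.1, with a signal of 196 ± 24.9 (SD, n = 4). The next lay in a UTR of Lars2 (chromosome 9, 123461901 to 123462120), a mitochondrial tRNA synthetase gene, at 115. The others of the top 5 were intergenic on chromosome 6 (49236421 to 49236620) at 98.7, in an intron of Zc3h7a (chromosome 16, 11144171 to 11144300) at 96.3 and intergenic on chromosome 3 (5860361 to 5860530) at 85.6. All 5 have near copies elsewhere in the assembly, from 1 to 15 of them, and how reads with several matches were placed is not given in the sources used here.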

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

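No test of a cause was made for the values in this part, and the rule that picked them was set before the data were examined. Of 238 groups of 4 libraries, 13 had a library far from the other 3 by Dixon's ratio at its 95% level. For independent, continuous values chance gives about 1 in 20, or 11.9 groups here. Many of these groups share data or are small whole counts, so 11.9 is not their chance level. In the 5 gene lists found and the median footprint width, 3 libraries tied, which fixes the ratio at 1. Replicate 1 was the library apart in 5 of them, replicates 2 and 4 in 3 each and replicate 3 in 2.

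Among gene lists, the share of open promoters of the homing and survival list was 92.3% in replicate 4 and 100% in the others. Germinal centre genes were at 80% in replicate 1 and 90% in the others, plasma cell genes at 75% in replicate 1 against 83.3%, and NK genes at 25% in replicate 1 against 33.3%. Stem and progenitor genes were at 70% in replicate 4 against 60%. Each of these 5 differences is 1 gene.

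Among named genes, the promoter of Ttn, the gene of the muscle protein titin, stood at percentile 47.0 in replicate 3 and from 8.88 to 11.9 in the others. Pecam1, an endothelial adhesion gene, was at 63.6 in replicate 1 against 73.6 to 75, and Foxp1, a transcription factor gene, at 80.5 in replicate 1 against 85.3 to 85.7. Among motifs, C/EBP stood at a log2 of 0.58 in footprints of replicate 2 against 0.81 to 0.84. For distal over promoter peaks, the E2A E-box was at 0.20 in replicate 4 against 0.16 to 0.17, and CRE at -2.82 in replicate 2 against -3.12 to -3.07. The median footprint width was 9 bp in replicate 2 and 10 bp in the others, and the widest footprint was 108 bp in replicate 3 against 98 to 99.

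The per-base FDR, which no comparison used, also marked sequence away from peaks. Of bases with an FDR under 0.05, 47.6% ± 2.02 lay outside the peaks (SD, n = 4), from 45.9% to 49.6%, or 18.9 ± 3.53 Mb. No control library gives a level for comparison.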

How the results depend on the processing

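Settings tried only after the data were seen were the 3 filters of peaks and genes and the ratio of receptor loci to the genome, and all other settings were planned. The peak count fell to 66592.5 per library in the stricter list and that of regions open in all 4 libraries to 45183. The log2 ratio of X to autosomes stayed below 0 under every setting tried, from -1.53 to -0.73. No paired analysis was possible because there is 1 group. The cause was not tested except where the construction of a setting gives it. Read depth is unknown. To reduce its effect, the same number of peaks, or for motifs of footprints, was taken from every library. How much of the effect this removes was not measured.

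Of a library's peaks, 62.9% were found in another with reciprocal overlap of 50%. Promoter minus distal reproducibility turned to -1.20, -3.15, -8.60 and -1.90 points in classes 2 to 5 of 5 equal classes of peak signal, with 1 sign over the libraries in classes 4 and 5 alone. The promoter share was 18.3% within 500 bp, 33.9% within 2500 bp, 31.4% in the stricter list and 27.9% without repeat peaks. By construction, keeping the wider footprints left 151268, of which 84.9% lay in peaks.

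For promoters of lists, 14 passed without matching. Within 500 bp erythroid (-19.7 points, adjusted p = 0.0369, permutation), neuron (-24.8) and hepatocyte lists (-26.9) passed and the myeloid list was at -1.41. Within 2500 bp early B (32.5) and germinal centre lists (30.2) passed and the activation list (18.3) did not. In the stricter list muscle (-31.2) passed, myeloid was at -0.511 and dendritic cell at -0.178. With the same number of peaks neuron (-26.0) and muscle (-27.8) passed. Without matching, T (-31.8), erythroid (-40.8), hepatocyte (-48.9), muscle (-47.9), NK (-30.1) and myeloid lists (-23.9) passed, and dendritic cell was at -1.25 and stem at 1.17. Leaving out 1 library put muscle between -27.2 (without replicate 2, adjusted p = 0.0342, permutation) and -21.6.

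For peaks per extended span, the hepatocyte list did not pass with the span alone (-1.01), 50 kb (-2.95), the stricter list (-1.44) or the same number of peaks (-1.71). Housekeeping did not pass with 50 kb (5.90), the stricter list (1.63), no matching (2.73), without replicate 3 (2.40, adjusted p = 0.0548, permutation) or without replicate 4 (2.40, adjusted p = 0.0724, permutation), and lay between 2.40 and 3.06 with 1 library left out. Lists that passed under no setting of this test turned direction: erythroid at -0.136 (span alone), -0.0319 (stricter list) and -2.01 (no matching), neuron at 0.616 (span alone) and 0.577 (no matching), NK at 1.08 (50 kb) and myeloid at -1.53 (no matching).

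Peaks per 100 kb in the stricter list and with the same number of peaks were 2.80 and 2.99 at Igh, 2.07 and 2.64 at Igk, 1.34 and 1.42 at Tra/Trd and 0.572 and 1.14 at Trg, and in the stricter list 8.28 at Igl and 1.2 at Trb, since both settings hold fewer peaks. Over the genome, Igh turned to -0.041 with the same number of peaks and Igk to -0.37 in the stricter list and -0.22 with the same number. Trg had no such value in the stricter list, where a library had no peak.

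With no reversed consensus, motifs in footprints turned for SPI1 (-0.29), RUNX (-0.047), NF-kB (0.081), the ETS-IRF composite (-0.010), SP/KLF (2.94), TCF/LEF (-0.35), GATA (-1.15) and HNF4 (-0.070), and in the wider footprints GATA was at -0.29. Distal over promoter turned for the interferon element (0.60), MEF2 (1.19), FOXO (0.71), NRF1 (-3.18) and HNF4 (0.50), and HNF4 was at 0.014 in the stricter list and between -0.13 and 0.018 with 1 library left out (0.017 without replicate 1, 0.018 without replicate 4). Of 97 named genes open in all libraries, 88, 97, 90 and 96 stayed so with 500 bp, 2500 bp, the stricter list and the same number of peaks, and of 35 open in none 35, 15, 34 and 35.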

Other observations

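Tests chosen after the result was seen were those of near copies at the strongest regions, a promoter close by, near copies of Y regions (with their random places) and T cell genes, and those of Y genes and neighbouring promoters were set before. Promoters of most protein-coding genes were open in these B cells. A promoter peak was present for 61.3% ± 0.857 of 21827 genes (SD, n = 4). It was present in all 4 libraries for 12763 genes and in none for 7622. Openness followed CpG content. Of 10 equal classes of genes by promoter CpG ratio, 8.94% were open in the lowest, 41.5% and 66.7% in classes 4 and 5, and 95.3% in the highest.

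The ranking of genes by accessible sites in the extended span made no correction for gene length. Foxp1, a transcription factor gene needed for B cell development, had 118.5 ± 21.1 peaks (SD, n = 4) and Bach2, which restrains plasma cell differentiation, 52.5 ± 5.92. Gm20388, a readthrough transcript model that spans 4434882 bp, had 465 ± 41.7, Fgfr2, annotated over 2960900 bp, 187 ± 28.2, Gse1 68.5 ± 9.26 and Tcof1 52.5 ± 12.1. The promoters with the strongest peaks were those of Dynlt1b (chromosome 17, 6430021 to 6430180), Sumo3 (chromosome 10, 77606461 to 77606660), Urb1 and H2-D1, an MHC class I gene (chromosome 17, 35262881 to 35263080). In a footprint of all 4 libraries at H2-D1, in its UTR, lay an NF-kB match, GGGGATTCCC (chromosome 17, 35262923 to 35262932). The region of Dynlt1b has 3 other near copies in the assembly and that of H2-D1 has 1, so their signal is not known to come from these places alone.

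The strongest shared regions mixed promoters with repeated sequence. Of the 50 strongest, 35 (70%) lay at a promoter against 302 of 1000 random shared regions (Fisher's exact test, p = 2.2e-08). Another near copy was present for 13 (26%) against 27 of 1000 (2.7%), a ratio of 9.63 (Fisher's exact test, p = 6.06e-09). The 50 include the regions whose repeated sequence prompted the test of copies, so this p is not independent of that observation. The overlap was small, with 2 promoter regions among the 13 with a copy and 33 among those with none. Reads of several copies collected at one place may therefore account for distal regions among the 50, of which 11 had a copy and 4 none, and no biological explanation was tested.

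Y chromosome peaks were present in all 4 libraries labelled female. Male cells argue for open promoters of Kdm5d, Eif2s3y, Uty and Ddx3y, genes expressed widely in male tissues and chosen outside the rule for names, and 0 of these 4 promoters had a peak in any library. Their spans extended by 10 kb held 1 peak each in replicate 3, and that of Eif2s3y also in replicates 1 and 2. A share of male cells too small for these lists of peaks to show stays open. Of the 107 Y regions, 86 (80.4%, exact 95% interval 71.6 to 87.4) had a near copy on another chromosome or unplaced sequence, but so had 82.1% of 1070 random places of the same lengths on Y (Fisher's exact test, p = 0.692). Of the 27 Y regions of all 4 libraries, 19 had such a copy (70.4%, interval 49.8 to 86.2). Of their random places 83.7% had one (Fisher's exact test, p = 0.107). The 8 regions with none, among them 90740981 to 90742260, all lay close together, between 90723681 and 90743960. The random places were spread over Y, and Fisher's test takes no account of such clusters. At the 8 regions with no such copy, its absence argues against reads from near copies on other chromosomes of this assembly. Copies shorter or less alike than the limits used here were not looked for. At Y regions with such a copy, reads from near copies elsewhere stay open as an explanation, since most Y sequence has such copies whether it holds a peak or not. No biological explanation was tested.

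Some T lineage promoters, among them Lck, Lat, Gata3 and Cd2, had a peak in all 4 libraries. T cells in the sample stay open as an explanation, since the T list went both ways. Of its 22 members, 8 (36.4%) had a promoter peak in at least 1 library and 14 in none. Among the 14, named after their values were seen, Cd3e, Cd3d, Cd3g, Cd4, Cd8a, Cd8b1 and Cd247 had none within 1 kb of a TSS, but the extended spans of Cd247, Cd4 and Cd3g held 11.5 ± 3.11, 5.25 ± 0.5 and 5 ± 0.816 peaks (SD, n = 4). The values argue against the promoter of a neighbouring protein-coding gene, since 0% of the 6 members open in all 4 libraries had their strongest promoter peak within 1 kb of the TSS of another such gene, the nearest lying 1581 bp away. Promoters of noncoding genes were not tested, and no biological explanation was tested.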
